A study of Caenorhabditis elegans with 2 samples.

How the data were processed

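ChIP-seq was done on mixed-stage embryos of a C. elegans strain with an eGFP-tagged unc-39 transgene, in 2 biological replicates, per the labels. The labels describe the immunoprecipitation as directed at eGFP-tagged UNC-39 and also list unc-39 as the antibody, so the antibody itself is not settled by the sources used here. The deposited files are 8 peak lists, 4 on build ce10 and 4 on build ce11. For each build there is a relaxed list per replicate and a relaxed list of the pooled replicates, both made as input for the irreproducible discovery rate (IDR) procedure, and the optimal list after the IDR threshold. Per the text files deposited with the samples, relaxed lists were derived from the alignments of the replicates and of a control, and the IDR list from the pooled list and both replicate lists. The control itself is not analysed here. The aligner, the peak caller, their settings and versions, and the read depth are not given in the sources used here.

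The deposited signal column is the score that the authors' peak caller gave each peak against its control. Its values were used only to rank or describe peaks within a list, because no scaling between libraries is recorded. The deposited −log10 q value column has many ties at its highest value (211 of 267 IDR peaks) and was used only as another ranking. The p-value column holds a placeholder in every peak and was not used. Peaks had 1 width per list on ce11 (376 bp in the IDR and pooled lists, 384 bp for replicate 1 and 356 bp for replicate 2), except for 1 peak in each of the IDR and pooled lists. Relaxed lists were made to contain background, so a peak in them is not a called region. The IDR list depends on both replicates, and how far the weaker one limits it is not known from the sources used here. Peaks on repeated sequence, such as gene copies, depend on how multiply mapped reads were treated, which is not given in the sources used here.

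The ce11 IDR list of 267 regions was analysed as the called regions, with the summit as position. Gene positions came from Ensembl release 115 on WBcel235, the assembly that ce11 names, sequence from the RefSeq copy of that assembly, and tRNA isotypes from the RefSeq annotation. No ce11 peak ran past the end of a reference chromosome. No coordinates were converted, and ce10 lists were used for counts, overlaps and shares per chromosome. Coordinates are 1-based.

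Replicates were compared by the overlap (at least 1 bp) of their 267 strongest peaks, and by the overlap of called regions with each library's list. Both libraries belong to 1 group, so no test between groups was possible. Summit shares were compared with 10000 random placements within the same chromosome, a permutation test on positions, where the smallest p is 0.0002 two-sided and 0.0001 one-sided. Random placement covers the whole chromosome, including sequence to which reads cannot be mapped uniquely. A promoter is the 1000 bp upstream of a protein-coding TSS, and noncoding RNA genes were searched within 200 bp. The 22 gene lists were tested over 19973 protein-coding genes with Fisher's exact test. The 8 motifs were searched on both strands within 100 bp of the summit and of points 500 bp to each side, with 1 mismatch allowed for MEF3 and the cyclic AMP response element. The result for 1 of them is not reported here, though it stays in the adjustment. Benjamini-Hochberg adjustment was applied within each family with a threshold of 0.05. Shares carry 95% Clopper-Pearson intervals, which cover counting error only. The low-signal comparison set was the lower-ranked part of the pooled list without regions that overlap a called one (4512 regions). GC-matched sets held 20 random windows per region, within 1 percentage point of GC content on the same chromosome (5340 windows).

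The tests, gene lists, motifs and the first set of other settings were fixed before the data were examined. Genes fixed in advance to be named were the protein-coding genes with a TSS within 1000 bp of the 25 strongest called summits. To these were added up to 4 members of each gene list by signal, and unc-39. Other genes were named after their values were seen. The first set of other settings used the 134 called regions of highest signal, or each library's 267 strongest peaks, as the called list. It also held other distances and windows, other comparison sets and the ce10 lists. Alternatives chosen after seeing the data were removing regions near small noncoding RNA genes or near tRNA genes, GC-matched windows, and counting summits in place of genes.

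The tests were tried on simulated data. Among 100 sets of random regions the TSS placement test called 5 and the motif sign test 4, and the gene list test called 2 of 100 random gene sets. With 25% of regions placed at TSSs, with 8 histone genes added, or with a motif written into 10% of windows, each test called all 100 sets. The 8-mer search recovered the added sequence in 20 of 20 sets and called 1 sequence in total in 20 sets of random regions. Random gene sets were drawn gene by gene, so that rate does not cover genes that share a summit. Random regions were not chosen for GC content, so the motif and 8-mer rates do not cover GC-rich summits such as the called ones. Calculations used Python 3.11.15, numpy 2.4.6 and SciPy 1.17.1, and plots matplotlib 3.10.9.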

Results

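Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where UNC-39 sits on the genome of Caenorhabditis elegans embryos. UNC-39 is a homeodomain transcription factor of the Six4 and Six5 type, known for roles in mesoderm differentiation, cell migration and the identity of the AIA interneurons. The animals carried a transgene that makes UNC-39 fused to green fluorescent protein, in an unc-119 mutant strain background, and whole embryos of mixed stage and sex were used. There was 1 group with 2 biological replicates, so the comparisons are between the replicate libraries, and between the called regions and the rest of the genome. In ce11 coordinates the list of called regions, which passed the authors' irreproducible discovery rate (IDR) threshold, held 267 regions. The relaxed list of the pooled replicates held 9046 regions, that of replicate 1 held 15880 and that of replicate 2 held 30000. The last number was the same on both genome builds, and whether that list ends at a set length is not given in the sources used here. The lists hold no read counts, so the sequencing depth is unknown, and the signal values quoted are the authors' own peak scores, used within a list only.

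The strongest called region lay 73 bp upstream of atx-2, the worm relative of the RNA-binding protein ataxin-2 (WBGene00000231, chromosome III, 10461128 to 10461503, promoter). It had a signal of 172.6 and ranked 1 in both replicate libraries. Further strong promoter regions sat between divergent histone genes. The region between his-61 and his-62 (chromosome IV, 7486347 to 7486440) had a signal of 132.8, and the region between his-31 and his-32 (chromosome IV, 8333965 to 8334340) had 108.9. The ribosomal protein gene rpl-3 (chromosome III, summit 293 bp upstream) had a signal of 112.9. Of the 25 strongest regions, 12 had a summit within 1000 bp of a protein-coding transcription start site (TSS). Besides those named, these lay near C04A11.5, tasp-1, ftt-2 (a 14-3-3 protein gene), hsp-3 (a chaperone gene of the endoplasmic reticulum), T02E1.2, tos-1, sre-23 and C18B12.4. Their signals ran from 86.9 to 172.6 over the 25 regions, and 6 of the 25 lay within 200 bp of a tRNA, snoRNA or snRNA gene, including the regions near C04A11.5, T02E1.2 and sre-23. All 25 were among the 267 strongest regions of each library.

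The first comparison asked how far the replicates gave the same regions. Of the 267 strongest regions of replicate 1, 120 (44.9%, 95% exact interval 38.9 to 51.1) overlapped one of the 267 strongest of replicate 2, and 119 (44.6%) did so in the other direction. Random placement of one list gave a mean of 0.556 shared regions and at most 6 (one-sided permutation p = 0.0001, the smallest that 10000 placements can give). The called list was derived in part from each library's relaxed list, which favours a high share here. Each relaxed list held 266 of the 267 called regions (99.6%). The 267 strongest regions of replicate 1 overlapped 182 of them (68.2%, interval 62.2 to 73.7), and those of replicate 2 overlapped 175 (65.5%, interval 59.5 to 71.2). Both top lists held 118 called regions, replicate 1 alone held 64, replicate 2 alone held 57 and neither held 28. Across 265 regions, which are not independent replicates, the signals of the libraries had a Spearman correlation of 0.185 (permutation p = 0.00286) and a Pearson correlation of 0.452 (permutation p = 1e-05, the smallest that 100000 permutations can give). The summits in the libraries lay a median of 32 bp apart. The called regions were chosen by the authors partly for agreeing ranks, so these correlations describe a selected set.

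The called regions lay at promoters more often than chance placement gave. Summits within 1000 bp of a protein-coding TSS numbered 146 of 267 (54.7%, 95% exact interval 48.5 to 60.8), against 40.2% ± 2.99 (SD over placements) at random (two-sided permutation p = 0.0002, the smallest possible). The median offset was 175.5 bp upstream of the TSS, with 121 upstream and 25 downstream, and 188 of 19973 protein-coding genes (0.941%) had a summit in this range. By annotation, 128 summits (47.9%) fell in promoters, within 1000 bp upstream of a TSS, against 21.8% at random. Exons of noncoding genes, a class that also covered pseudogene exons, took 37 summits (13.9% against 2.60%). Each summit was given to a single class, with promoters first, then UTRs, coding exons, noncoding exons, introns and intergenic sequence. Fewer summits than at random fell in introns (39, 14.6% against 29.1%), coding exons (5, 1.87% against 20.7%) and 3′ UTRs (1, 0.375% against 2.67%). The adjusted p was 0.00035 for the promoter, noncoding exon, intron and coding exon classes and 0.0157 for the 3′ UTR class (random placement as a permutation test, two-sided, Benjamini-Hochberg over the classes). Intergenic sequence held 57 (21.3% against 22.1%, adjusted permutation p = 0.829) and no summit fell in a 5′ UTR (adjusted permutation p = 0.118). With the strongest regions of replicate 2 alone, coding exons held 7.49% and the noncoding exon class 8.61%, both still past the threshold. Regions of the pooled list with low signal were also often near a TSS (45.7% of 4512), and the called regions exceeded this share (Fisher's exact test, two-sided, p = 0.00447).

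**Figure D1:**
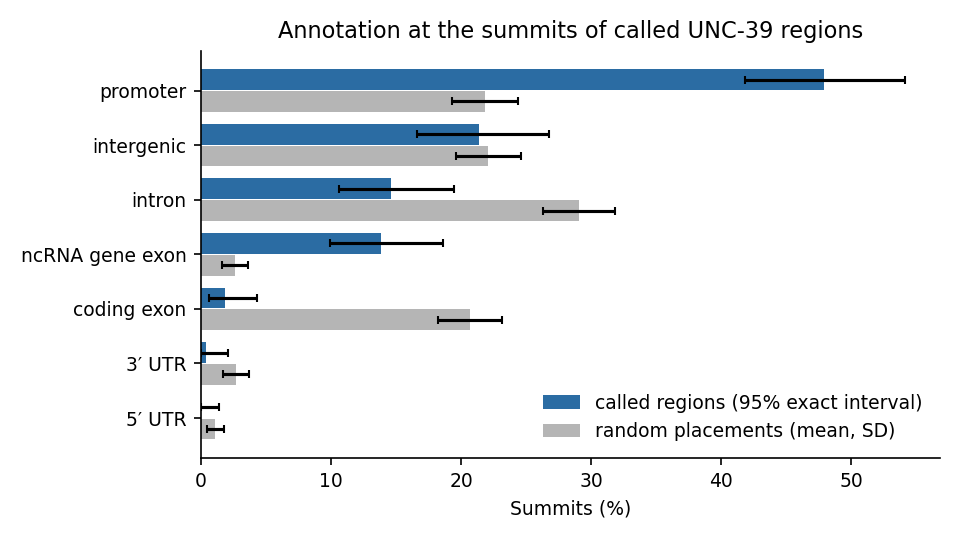
Percentage of the 267 called summits in each annotation class (blue, with 95% exact intervals) and the mean over 10000 random placements (grey, with SD). Promoters held 47.9% of the summits against 21.8% at random, and coding exons 1.87% against 20.7%. The class of noncoding RNA gene exons also covers pseudogene exons.

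Genes for small noncoding RNAs stood out among the called regions. A tRNA gene lay within 200 bp of 37 summits (13.9%, 95% exact interval 9.95 to 18.6), 44.1 times the random mean of 0.839 summits. A snoRNA gene, whose product guides the chemical modification of other RNAs, lay within 200 bp of 26 summits (9.74%, interval 6.46 to 13.9), 53.8 times the random mean. For snRNA genes there were 4 summits (1.498%, interval 0.410 to 3.79, 27.6 times the random mean), and the 3 genes near them, sls-2.1, sls-2.2 and sls-2.4, encode spliced leader RNAs that are joined to the start of many worm messenger RNAs. These 3 genes were named after their values were seen. Each of the 3 classes had an adjusted p of 0.000267 (random placement as a permutation test, two-sided, Benjamini-Hochberg over 4 classes), and no summit lay near the 20 annotated rRNA genes. With the strongest regions of 1 library in place of the called list, the tRNA share was 8.61% for replicate 1 and 9.36% for replicate 2, still past the threshold. For replicate 2 the snRNA share was 0.375% and was not past the threshold (adjusted permutation p = 0.376).

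The 41 tRNA genes near a summit were a small part of the 612 annotated (6.70%), and they covered 18 of 21 tRNA isotypes with at most 5 genes each. The strongest tRNA region lay on chromosome X at a leucine tRNA gene (WBGene00000308, 13665555 to 13665673) with a signal of 111.6, and the strongest snoRNA region lay on chromosome V at T03F7.8 (11314258 to 11314332) with 138.7. These were picked out after their values were seen. Of the 346 snoRNA genes 27 were near a summit (7.80%). Among the low-signal regions of the pooled list only 0.687% lay near a tRNA gene, 0.355% near a snoRNA gene and 0.111% near an snRNA gene. The called regions exceeded these shares (Fisher's exact test, two-sided, p = 1.81e-29, 6.07e-23 and 0.00096).

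**Figure D2:**
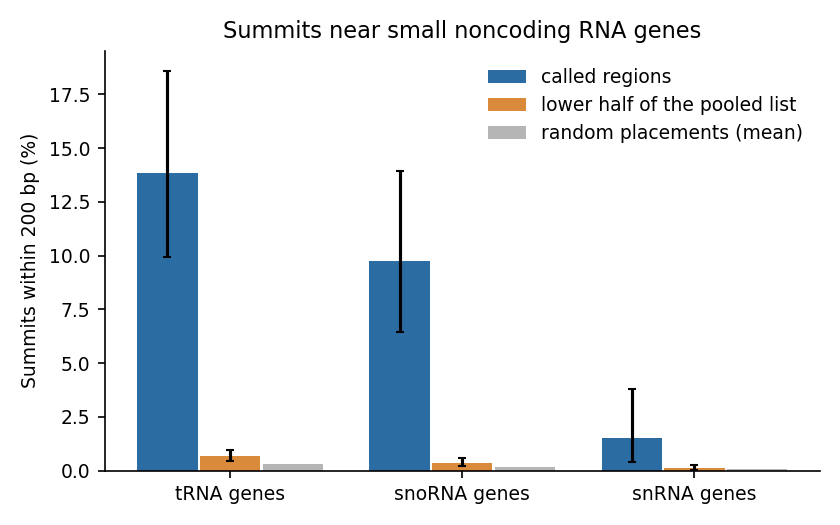
Percentage of summits within 200 bp of a tRNA, snoRNA or snRNA gene in the called regions (blue), the 4512 low-signal regions of the pooled list (orange), both with 95% exact intervals, and random placements (grey, mean). The called regions reach 13.9% for tRNA genes and 9.74% for snoRNA genes, and the other sets at most 0.687%.

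Chromosome X carried more called regions than its length gives, and chromosomes IV and V carried fewer. X held 69 summits (25.8%, 95% exact interval 20.7 to 31.5) on 17.7% of the length (adjusted exact p = 0.00563). Chromosome IV held 29 (10.9% against 17.4%, adjusted exact p = 0.0108) and V held 40 (14.98% against 20.9%, adjusted exact p = 0.0385). Chromosomes I, II and III, with 42, 41 and 46 summits, were not past the threshold (exact binomial tests, two-sided, Benjamini-Hochberg over 6 chromosomes). Of the 37 summits near tRNA genes 21 lay on X, where 45.1% of tRNA genes are annotated, and none of the 26 near snoRNA genes did. Without the summits near tRNA genes the X share was 20.9% (adjusted exact p = 0.277). Among the 134 regions with the highest signal it was 26.9% (adjusted exact p = 0.0521), and the IV and V calls were lost there and with either library alone.

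Histone, ribosomal protein and heat shock genes made up the gene lists that stood above the genome. A summit lay within 1000 bp of a TSS of 8 of 72 histone genes (11.1%, odds ratio 13.7, adjusted exact p = 8.36e-06). These 8 were 4 divergent pairs that share 4 summits, his-61 with his-62, his-31 with his-32, his-67 with his-68 and his-59 with his-60, of which the last 4 genes were named after their values were seen. The region between his-61 and his-62 is the called region with a width other than 376 bp. Whether reads shared between gene copies add to the signal at histone genes was not tested. Nor was it tested for any list whether the signal is particular to UNC-39, as no other factor was analysed. Of the ribosomal protein genes 6 of 79 had a summit (7.59%, odds ratio 8.90, adjusted exact p = 0.00111), with signals of 112.9 at rpl-3, 80.7 at rps-28, 68.7 at rpl-12 and 67.1 at rpl-35. One of the 6, rpl-27, was counted from a summit past its 3′ end, 45 bp upstream of the neighbouring gene egl-30, in a region that no peak of replicate 1 overlapped (signal 46.8), and was named after its values were seen. Heat shock genes followed with 3 of 22 (13.6%, odds ratio 16.9, adjusted exact p = 0.00609), namely hsp-3 with a signal of 103.0, hsp-1, a cytosolic Hsp70 gene, with 47.3, and hsp-60, a mitochondrial chaperonin gene, with 45.9. The summit counted for hsp-60 lay 661 bp from its TSS and 152 bp from that of Y22D7AL.10, and its region ranked 2445 in replicate 1. Chemoreceptor genes, a large family used in smell and taste, were under-represented with 2 of 1309 (0.153%, odds ratio 0.152, adjusted exact p = 0.00387), sre-23 and sre-1. The summit near sre-23 also lay within 200 bp of a snoRNA gene, and that near sre-1 lay 944 bp from its TSS and 50 bp from that of B0495.9. These closer neighbours were named after their values were seen.

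The test was Fisher's exact test, two-sided, over 19973 protein-coding genes with Benjamini-Hochberg adjustment over 22 lists, and genes that share a summit are not independent. Against genes that had a relaxed summit of the pooled list, the ribosomal protein call was lost (odds ratio 3.10, adjusted exact p = 0.141), as was the chemoreceptor call (odds ratio 0.359, adjusted exact p = 0.771). With the strongest regions of replicate 2 alone, histone genes had an odds ratio of 8.36 (adjusted exact p = 0.00545), and chemoreceptor genes had 0.236 and 0.239 with either library alone. The heat shock call was lost with either library alone (odds ratios 10.9 and 11.05, adjusted exact p = 0.094 and 0.0921).

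None of the lists tied to the known roles of UNC-39 was past the threshold at 1000 bp. Of 26 mesoderm and myogenic regulators only ceh-20, a homeodomain cofactor gene of the Pbx type, had a summit in range (3.85%, odds ratio 4.23, adjusted exact p = 0.685), 701 bp upstream of the TSS with a signal of 45.1, and it was also the only one of 97 homeobox genes (adjusted exact p = 1). Of 60 axon guidance and cell migration genes 2 had a summit in range (3.33%, odds ratio 3.66, adjusted exact p = 0.402), and within 2000 bp there were 5 and the list was past the threshold (odds ratio 6.22, adjusted exact p = 0.0101). The 2 within 1000 bp were mom-5, which encodes a Frizzled receptor for Wnt (signal 48.5), and lam-1, which encodes laminin beta (signal 46.5), where the summit lay past the 3′ end of the gene, 919 bp downstream of the TSS of a short annotated transcript. The TSS nearest to that summit was that of W03F8.4, 291 bp away. No gene had a summit among 47 muscle structure genes (upper exact limit 7.55%), 10 AIA identity genes (30.8%), 19 pan-neuronal genes (17.6%) or 6 genes of the sine oculis, Eya and Dach families (45.9%). None did among 20 intestine, 22 germline, 14 pharynx, 21 T-box, 33 proteasome, 20 V-ATPase and 322 F-box genes either. Single genes were found among 167 cuticle collagen genes (col-85), 269 nuclear receptor genes (nhr-48), 39 bHLH genes (mdl-1) and 140 neuropeptide genes (flp-15). The summit counted for col-85 lay inside an isoleucine tRNA gene, and the region counted for nhr-48 ranked 1603 in replicate 2. The smallest adjusted p of the 18 lists that were not past the threshold was 0.35.

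**Figure D3:**
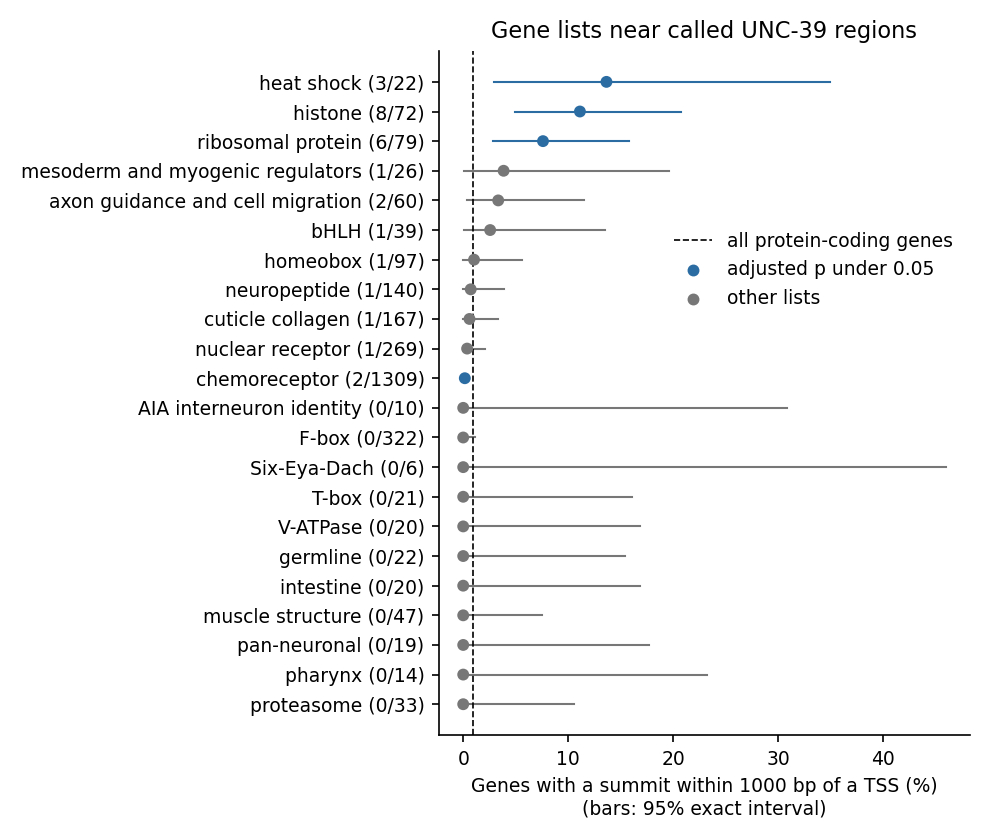
Percentage of the genes of each list with a called summit within 1000 bp of a TSS (points, with 95% exact intervals), with the number of genes beside each name and the share of all protein-coding genes, 0.941%, as a dashed line. Heat shock, histone and ribosomal protein genes lie above the line and chemoreceptor genes below it (blue, adjusted p under 0.05), and the intervals of the other 18 lists reach the line.

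Among the motifs fixed in advance, a GA repeat had the smallest p at summits, and the motif known for Six4-type proteins was found at fewer summits. The sequence GAGAGAGA lay within 100 bp of 34 summits (12.7%) against 1.87% of the flanking windows 500 bp away (adjusted exact p = 4.83e-06), and against 2.53% of random windows matched on GC content (adjusted exact p = 2.06e-12). The Six4-type sequence TGACACC lay at 13 summits (4.87% against 0.936%, adjusted exact p = 0.0163), but against GC-matched windows it was not past the threshold (2.98%, adjusted exact p = 0.211). The E-box CAGCTG was more frequent at summits than in flanks (8.99% against 3.75%, adjusted exact p = 0.0447). Within 50 bp of the summit the difference was 0.375 percentage points (adjusted exact p = 1), and the call was lost with either library alone. MEF3 (2.62% against 6.74%, adjusted exact p = 0.0163), GATA (4.49% against 7.87%, adjusted exact p = 0.0447) and runs of T (7.87% against 21.3%, adjusted exact p = 0.000155) were less frequent at summits than in flanks. Against the left flank alone MEF3 and GATA were not past the threshold (adjusted exact p = 0.23 and 0.743). None of these 4 was past the threshold against GC-matched windows, and for runs of T the direction turned (7.13% in those windows). A cyclic AMP response element lay at 22 summits (adjusted exact p = 0.355). Flanks were compared by an exact sign test against the right flank, with both flanks averaged for the percentages, and GC-matched windows by Fisher's exact test, two-sided, each adjusted over 8 motifs. The 201-bp windows at the called summits had a GC content of 47.2% ± 6.37 (SD over 267 regions), above 39.7% ± 6.67 in the 4512 low-signal regions and 35.4% in the genome.

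**Figure D4:**
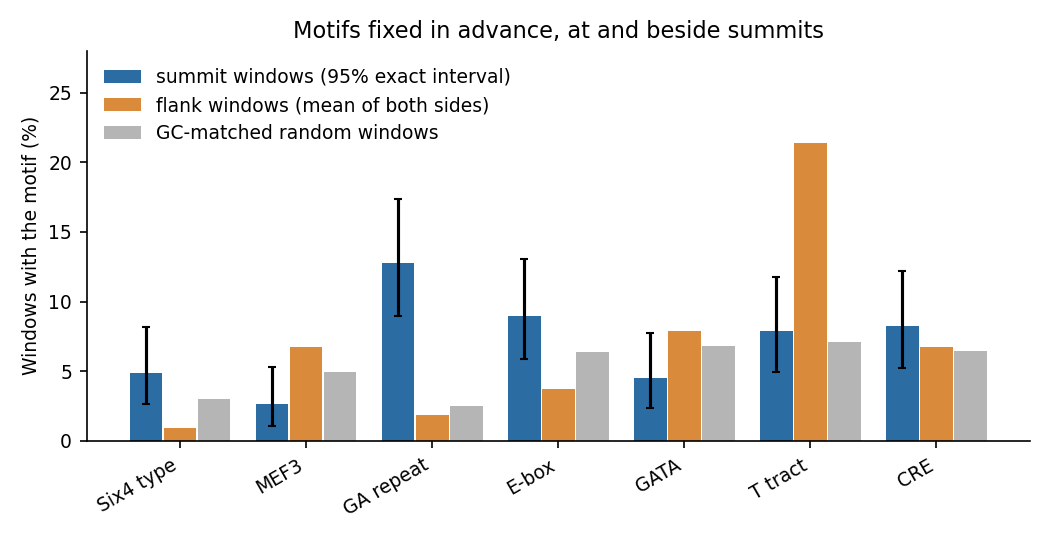
Percentage of windows that hold each motif reported here at the called summits (blue, with 95% exact intervals), in the flanks (orange, mean of both sides) and in GC-matched random windows (grey). The GA repeat stands at 12.7% of summits against 1.87% of flanks and 2.53% of GC-matched windows.

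A search over all 8-base sequences found 122 of 249 tested ones more often at summits than in the right flank (Fisher's exact test, one-sided, Benjamini-Hochberg). The smallest p was that of GAGACGCA, at 29 summits and in 1 flank (adjusted exact p = 3.39e-06). Among regions away from tRNA, snoRNA and snRNA genes, it lay at 15 of 121 near a protein-coding TSS and 12 of 79 farther from one. It lay at 1 of 37 tRNA regions and 1 of 26 snoRNA regions. GGGTTCGA, which matches the internal promoter of tRNA genes, lay at 20 summits and in 1 flank (adjusted exact p = 0.000312). It was found at 16 of the 37 tRNA regions and 4 of the 26 snoRNA regions, and at none of the 121 and 79 other regions. Sequences overlap one another and were tested only if present at 10 or more summits, which favours summits. With the left flank in place of the summit, 0 of 476 sequences were past the threshold. Both windows there are flanks, so this does not cover base composition particular to summits. Against GC-matched windows, a comparison chosen after seeing the data, all 122 were past the threshold.

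At the unc-39 gene itself (WBGene00006775, chromosome V, 14373074 to 14375881, plus strand, 4 exons) no called region lay within 20 kb, where an even spread would give 0.114. The relaxed pooled list had 2 regions there, where an even spread would give 3.86. The stronger of them lay 17007 bp upstream with a signal of 27.98 and ranked 1576 of 9046. The relaxed lists of replicate 1 and replicate 2 had 3 regions each, against 6.78 and 12.8 for an even spread of lists of their length. The transgene adds copies of unc-39 sequence, so signal near this gene cannot be assigned to the chromosomal locus alone.

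The same libraries were also processed by the authors on the older build ce10. There the called list held 280 regions against 267, the pooled list 9289 against 9046, and replicate 1 held 15620 against 15880, while replicate 2 held 30000 on both. Chromosome X held 25.7% of the called regions on ce10 and 25.8% on ce11.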

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

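Of 181 alternatives to 31 main results, 117 were scored as unchanged, and of 187 alternatives to 26 other results 185 were. A main result with a test had to keep its direction and its side of the threshold. Counts of calls and shares without a test only had to stay near the main value. For example, 3 gene list calls in place of 4 were scored as unchanged. Other results with a test only had to stay short of the threshold, and their direction could turn. For 4 alternatives to gene lists no odds ratio existed, as no list member was counted on either side. Kept under every alternative run were the replicate overlap (36.9% to 46.6%) and the TSS share (39.7% to 72.3%, with the distance). So were the promoter, intron, coding exon and noncoding exon classes, tRNA genes (8.61% to 14.2%) and snoRNA genes (9.74% to 14.2%). Histone genes (odds ratio 8.36 to 21.1) and the GA repeat (7.49 to 13 percentage points above the comparison set) were kept as well. Read depth is unknown. Removing regions near small noncoding RNA or tRNA genes, GC-matched windows and counting summits were chosen after seeing the data. No paired analysis was possible because there is 1 group. Unless a reason is given, the cause was not tested.

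With only the 134 called regions of highest signal, fewer regions were tested. Each library's top list then held 94.8% (replicate 1) and 88.1% (replicate 2) of them, which follows from the selection by signal. The 3′ UTR share was 0% (adjusted permutation p = 0.0826). There were 0 chromosome calls, with shares of 13.4% on IV, 15.7% on V and 26.9% on X (adjusted exact p = 0.387, 0.387 and 0.0521). There were 2 gene list calls, histone and ribosomal protein genes, and calls were lost for heat shock (odds ratio 9.36) and chemoreceptor genes (0.284). There were 2 motif calls, the GA repeat and the Six4 type, and calls were lost for MEF3 (-3.73 points from the flank), E-box (5.97), GATA (-4.48) and the T tract (-8.96). Called 8-mers numbered 13.

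With 1 library's strongest regions in place of the called list, there was 1 chromosome call each (X, 24.7% to 26.6%), with 13.1% to 13.9% on IV and 16.1% to 16.5% on V. The heat shock odds ratio was 10.9 to 11.05 and the snRNA share 0.375% to 1.498%, lowest without replicate 1. Heat shock, MEF3, E-box and GATA lost their calls with either library. Motif calls numbered 2 to 3, with differences of 3.75 to 5.99 points for the Six4 type, -4.49 to -2.62 for MEF3, 3.75 to 4.12 for E-box and -5.62 to -2.25 for GATA. The Six4 call was lost without replicate 1 (adjusted exact p = 0.0567). Without each library in turn, 67 and 81 of the 122 called 8-mers were called again among 117.

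Without regions near small noncoding RNA genes there were 0 chromosome calls (IV 12%, V 15.5%, X 24%), and without those near tRNA genes also 0 (IV 11.7%, V 16.96%, X 20.9%). The first of these lost the calls for the Six4 type (3.5 points) and E-box (5.5) and gave 68 8-mers, 65 of them among the 122. The cyclic AMP response element was then past the threshold (6 points, adjusted exact p = 0.0463). Among genes with a relaxed pooled summit there were 2 gene list calls, histone and heat shock genes, and calls were lost for ribosomal protein (odds ratio 3.10) and chemoreceptor genes (0.359). Counting summits against low-signal regions also lost the chemoreceptor call (0.418). At 2000 bp the axon guidance list was past the threshold with 5 genes (odds ratio 6.22, adjusted exact p = 0.0101).

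With a 50 bp motif window there were 3 motif calls (GA repeat, T tract and GATA), and calls were lost for the Six4 type (3.00 points), MEF3 (-3.37) and E-box (0.375). With the left flank the MEF3 (-2.62) and GATA (-1.498) calls were lost, and against low-signal regions those of the Six4 type (1.68) and GATA (-3.51). Against GC-matched windows there was 1 motif call, the GA repeat. Calls were lost for the Six4 type (1.89), MEF3 (-2.32), E-box (2.62) and GATA (-2.34), and the T tract reversed to 0.730. That comparison set removes differences in GC content by construction. It called 189 8-mers, all 122 among them, with 20 windows per region.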

Other observations

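Noncoding genes outside the 4 classes chosen in advance also lay near called regions. The annotation leaves 7764 genes in an unspecified noncoding class, and 72 summits (26.97%, 95% exact interval 21.7 to 32.7) lay within 200 bp of one, against 3.73% at random (placement test, two-sided, p = 0.0002, the smallest possible) and 6.94% of low-signal regions (Fisher's exact test, p = 7.38e-22). Among these genes were rpr-1, the RNA of RNase P, which trims the ends of tRNAs (signal 46.8), mrpr-1, the RNA of RNase MRP (signal 48.8), and srpr-2.2, an RNA of the signal recognition particle (signal 44.9). Of the 72 summits 36 also lay near a tRNA, snoRNA or snRNA gene, and among the 200 regions away from those genes 36 (18%, interval 12.9 to 24.0) lay near one of the unspecified class. The called regions also included cel-mir-51 (signal 82.0) and cel-mir-52 (signal 75.996), both microRNA genes of the mir-51 family. These genes were picked out after their values were seen.

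The 6 lists tied to mesoderm, muscle and neurons were also pooled after the data were seen. Of their 162 distinct genes 3 had a summit (1.85%, 95% exact interval 0.384 to 5.32), against 0.941% of all protein-coding genes (Fisher's exact test, two-sided, p = 0.196, odds ratio 2.00).

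The tests below were run after the patterns were seen, and those on tRNA regions for chromosome X and on the ranks of unshared regions were chosen only after the result was seen. No biological explanation was tested, because the design has 1 group and the control is not analysed here.

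The share of called regions at tRNA genes (13.9%) and snoRNA genes (9.74%) was weighed against GC content, and that at tRNA genes also against shared reads. Random windows matched on GC content and chromosome lay within 200 bp of a tRNA gene in 0.581% of cases (95% exact interval 0.395 to 0.823) and of a snoRNA gene in 0.393% (interval 0.244 to 0.601), which argues against GC content as the source. In the 376 bp around the 41 tRNA genes near a summit, 84.2% ± 3.14 (SD over genes) of 31-base sequences were unique in the genome, and around the other 571 tRNA genes 82.3% ± 12.1. The difference of 1.91 percentage points (permutation test, two-sided, p = 0.313) leaves open whether reads shared between gene copies could add to the signal at tRNA genes, since the treatment of such reads is not given in the sources used here. Open chromatin that draws signal in many ChIP experiments may be another source, and it was not tested.

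The excess on chromosome X (25.8% of regions on 17.7% of the length) was weighed against GC content and the position of tRNA genes. Of the GC-matched windows drawn from the whole genome, 15.8% fell on X (95% exact interval 14.8 to 16.8), so GC content would give fewer regions there, not more. Without regions near tRNA genes the X share was 20.9% (48 of 230, 95% exact interval 15.8 to 26.7, exact binomial p = 0.196). That interval holds both the share of length and the full share, so it cannot be told apart whether tRNA genes on X account for the excess. None of the 26 regions at snoRNA genes or the 4 at snRNA genes lay on X, so keeping them lowered the 20.9%. Of the 200 regions away from tRNA, snoRNA and snRNA genes 48 lay on X (24%), close to the full 25.8%. After adjustment over the chromosomes this share was not past the threshold (exact binomial test, adjusted p = 0.081). The p of 0.196 above was not adjusted, so these p-values cannot be compared directly.

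Of the 267 strongest regions of replicate 1, 44.9% were shared with replicate 2. The 147 unshared regions of replicate 1 had a GC content of 44.4% ± 6.41 (SD over regions) and the 148 of replicate 2 had 49.0% ± 5.94 (permutation test, two-sided, p = 1e-05, the smallest possible). Ranking the regions of each library within 5 bins of GC content left the shared percentage at 43.8%, inside the interval of 38.9 to 51.1. The bin limits came from the whole relaxed list of replicate 1, and GC content was not matched within a bin. The highest bin had no upper limit, so the ranking cannot decide whether GC preference caused the low overlap. Unshared regions did not sit just past the end of the other list, since their median rank there was 2361 for replicate 1 and 2512 for replicate 2, beyond 801, and 25.9% and 28.4% lay within that rank. A difference in depth or enrichment between the libraries may remain and was not tested, as the lists hold no read counts.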
